A study of Rattus norvegicus with 8 samples.

How the data were processed

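MicroRNA (miRNA) was measured in remnant kidney cortex from 8 male Sprague-Dawley rats, 4 given L-mimosine and 4 given vehicle, each on 1 one-colour Agilent rat miRNA array labelled with Cy3. Groups and replicate numbers were taken from the sample titles, and the design text gives 4 rats for each group, so the replicates are separate animals. Per the file headers, the authors scanned the arrays and quantified the spots with Feature Extraction 10.5.1.1, and each deposited array table holds spot intensities on a linear scale, among them the background-subtracted processed signal, the mean signal, the local background and the total signal per miRNA, together with 0 or 1 flags for detection, outliers and saturation. The deposited series matrix holds the authors' processed values on a log2 scale. Its unit is not stated, and comparison with the array tables showed it to follow the total signal per miRNA with the same sorted values in every array, as quantile normalization gives. Any further step the authors took is not given in the sources used here.

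Each array carried 7953 spots, of which 7000 belonged to 938 probes for 350 rat miRNAs and 953 were controls. Control spots and spots with an outlier flag were left out, between 124 and 262 spots per array. The processed signal was averaged over the spots of a probe and summed over the probes of a miRNA. A miRNA was called detected on an array when at least 1 of its probes had more than 50% of its spots well above background. Because 28.3% of the miRNAs were detected on all 8 arrays, each array was divided by the 75th percentile of those 99 miRNAs. Values were then floored at the median over arrays of the lowest scaled value of a detected miRNA, -6.15 on the log2 scale, and taken to log2, so 0 is the level of that percentile. Values at the floor have no order. The 127 miRNAs detected on at least 4 of the 8 arrays, whatever the group, were tested.

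Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates) and Benjamini-Hochberg adjustment over the 127 miRNAs, at an adjusted p of 0.05. Single miRNAs also had a two-sided exact permutation test of 4 against 4 arrays, whose 70 assignments allow no p below 0.0286. Of 19 miRNA lists, the 12 with at least 3 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 12, and again with camera at an estimated correlation and with fry. The lists covered the miR-29 family, hypoxia-responsive and profibrotic miRNAs, the miR-200, miR-30, let-7 and miR-15/16 families (the latter with miR-195, miR-497 and miR-322), the miR-17/92 and miR-23/24/27 clusters, and markers of kidney tubule, leukocytes, smooth muscle and fibroblasts. Lists for erythrocytes, endothelium, striated muscle, adrenal and neuroendocrine cells, liver, neurons and the Dlk1-Dio3 locus had fewer than 3 tested members. The groups, tests, lists, named miRNAs and most alternatives were fixed before the data were examined.

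The miRNAs named are every miR-29 family member on the array and miR-210, those past the adjusted threshold, the smallest unadjusted p-values until 20 are named, 2 tested members of each list with the smallest unadjusted p, and the 5 miRNAs with the highest mean signal. Others are said where they occur to have been chosen after their values were seen. miRNA names are those of the array design and can be old. Of the 127 tested miRNAs, 124 matched a gene in the RefSeq table of the rat assembly GRCr8, which was used only to find which miRNA genes neighbour each other, within 10 kb. The files name no genome build, and gene positions were used for nothing else here.

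The steps were tested on simulated data drawn from the means and spreads of the 127 miRNAs, in 50 simulations of 4 against 4 arrays. The fit recovered 39.2% of miRNAs changed by 1.5-fold, 80.4% of those changed by 2-fold and 97.2% of those changed by 4-fold, and 3.99% of its calls were false. In these simulations many miRNAs changed at once, which eases the Benjamini-Hochberg threshold, and the miRNAs varied independently of each other. The shares recovered may therefore not hold for the real arrays. In further simulations without change, the deviations of whole real arrays were drawn at random with replacement and with random sign. Camera at the preset correlation then called at least 1 list in 40 of 50, and the miR-29 list in 3 of 50. The same array could recur in a simulated group, unlike the separate animals here, so these rates may not hold for the real arrays. The number of arrays limits the precision: the median 95% interval of a log2 difference reached 0.49 to either side.

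Alternatives covered scaling between arrays, background correction, the summary over probes, the authors' series matrix values, detection and the filter on dim miRNAs, the floor, a block for the replicate number, the moderation of the fit, array weights, the list test, and leaving out each array in turn. Slide row as a block and scaling to 14 bright positive control probe sets were added after seeing the data, as was camera at an estimated correlation in 4 alternatives that added lists. All 8 arrays came from 1 slide and 1 scan, so slide or scan as a block could not be run.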

Results

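Remnant kidney cortex was profiled in rats that had undergone 5/6 nephrectomy, the removal of most kidney mass, after which the remaining tissue scars. From week 4 to week 12 the rats received vehicle or L-mimosine at 50 mg/kg every other day. L-mimosine inhibits prolyl hydroxylases, the enzymes that mark hypoxia-inducible factors for breakdown. The study's title concerns miR-29c in fibrotic kidney, and the deposited arrays ask how the miRNAs of the remnant cortex differ between the treatments. Vehicle-treated rats were the controls, and intact kidney was not analysed here.

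Detected miRNAs numbered 100, 129, 120 and 136 on L-mimosine arrays 1 to 4 and 136, 120, 126 and 127 on vehicle arrays 1 to 4. The means were 121 ± 15.6 and 127 ± 6.60 (SD, n = 4 each), which did not differ (exact permutation p = 0.686, two-sided). The 75th percentile signal, the scaling reference, was 1294 ± 493 intensity units with L-mimosine and 1214 ± 266 with vehicle (exact permutation p = 0.857, two-sided, n = 4 each). No miRNA spot was saturated. Of the 350 miRNAs, 202 were detected on no array, 21 on 1 to 3 arrays and 99 on all 8. No miRNA was detected on all arrays of 1 group and none of the other. The 5 miRNAs with the highest signal were miR-21, let-7a, let-7c, let-7f and let-7b, though signals of different probes do not measure relative abundance. Array pairs correlated between r = 0.913 and 0.992 across the tested miRNAs, which are not independent replicates.

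The miR-29 family, which represses collagens and other matrix genes, stood higher with L-mimosine than with vehicle in all 4 tested members. As a list it was called higher at the preset correlation of 0.01 (camera adjusted p = 4.87e-05, mean log2 difference 0.54), although no member passed the test by itself. The correlation estimated among its members was 0.36, and with that the call was lost (camera adjusted p = 0.170). It was also lost with fry (adjusted p = 0.203), and a permutation of the list mean gave an exact p of 0.0857 (two-sided, n = 4 each). miR-29c measured 0.11 ± 0.50 on the log2 scale with L-mimosine and -0.58 ± 0.18 with vehicle (SD, n = 4 each), a 1.62-fold difference. Its log2 difference was 0.69 (SE 0.25, 95% interval 0.13 to 1.25), and L-mimosine arrays were higher in 15 of the 16 array pairs. miR-29b differed by 0.72 (SE 0.32; 0.46 without L-mimosine 4, 0.47 with array weights), miR-29c* by 0.44 (SE 0.20; 0.29 without vehicle 1, 0.13 with normexp background correction) and miR-29a by 0.31 (SE 0.25; 0.07 without vehicle 3, 0.12 with array weights, 0.51 with median scaling). The star strands miR-29a*, miR-29b-1* and miR-29b-2* were detected on no array.

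**Figure D1:**
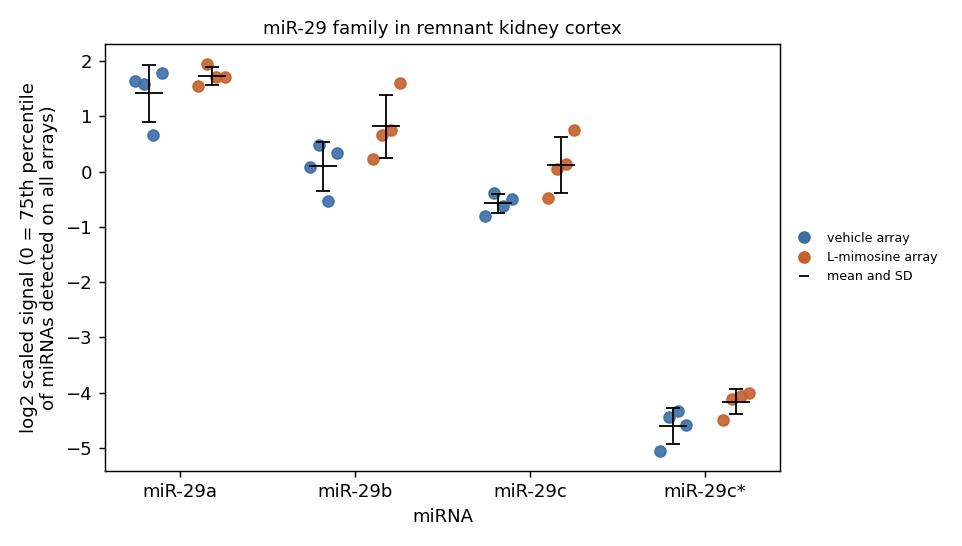
The log2 scaled signal (vertical axis) is plotted per array for the 4 tested miR-29 family members (horizontal axis), with vehicle arrays in blue, L-mimosine arrays in orange and bars for mean and SD (n = 4 per group). Mean log2 differences lie between 0.31 for miR-29a and 0.72 for miR-29b, and the groups overlap in each member.

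For miR-29c the limma p was 0.0215 before adjustment and 0.378 after Benjamini-Hochberg adjustment over 127 miRNAs, and the exact permutation p was 0.0571 (two-sided, n = 4 each). The lowest p in the family was 0.0715 adjusted over the list alone, with 0 of 4 members past the threshold either way. The study's title names miR-29c, so this list is not independent evidence of its direction. Slide row 1 held 3 L-mimosine arrays and 1 vehicle array, and row 2 held 1 and 3. The miR-29c difference was 0.70 within row 1, 1.26 within row 2 and 0.98 with row as a block (limma adjusted p = 0.149). The only vehicle array of row 1, vehicle 1, was the lowest vehicle array (-0.80). The only L-mimosine array of row 2, L-mimosine 4, was the highest L-mimosine array (0.75), and without it the overall difference was 0.48. These row values therefore rest largely on single arrays. The 2 probes of miR-29c differed by 0.72 and 0.67 between the groups. Over their shared length the miR-29a and miR-29c probes differ by G13A, counted from the 5′ end of the miR-29a probe, and they share 12 bases in a row. The miR-29b and miR-29c probes share 16, so signal shared among these 3 members cannot be excluded.

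Among the other miRNAs, limma found 0 of 127 past an adjusted p of 0.05. The lowest adjusted p was 0.310, and 12 had an unadjusted p under 0.05 where 6.35 were expected by chance. Of these 12, miR-29c was higher with L-mimosine and 11 were lower: miR-322*, miR-181d, miR-145, miR-466b, miR-320, miR-872, miR-181c, miR-196c, miR-196a, miR-152 and miR-93. Among them miR-466b differed by -0.88 (SE 0.29), miR-322* by -0.71 (SE 0.18) and miR-145, a miRNA of smooth muscle, by -0.50 (SE 0.15). miR-322*, miR-181d, miR-320 and miR-872 were detected on 2 of the 4 L-mimosine arrays and miR-181c on 1, so their differences rest partly on signals below detection. With the floor doubled, miR-322* differed by -0.04, miR-181d by -0.02, miR-320 by -0.03, miR-181c by -0.03, miR-145 by -0.15 and miR-466b by -0.56. With normexp background correction miR-322* differed by -0.17, miR-145 by -0.11, miR-466b by -0.24 and miR-872 by -0.12, and miR-145 by -0.17 with quantile normalization and in the authors' series matrix and -0.30 with median scaling. With the mean of the probes' log2 values miR-322* differed by -0.35, miR-145 by -0.20 and miR-466b by -0.39, and miR-322* by -0.47 without scaling and miR-466b by -0.56 in the series matrix. The groups did not overlap in 7 miRNAs, namely miR-322*, miR-181d, miR-145, miR-466b, miR-872, miR-196a and let-7f, against 3.63 expected from a chance of 2.86% each.

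The median log2 difference over the 127 miRNAs was -0.16, and 90 of them (70.9%) were lower with L-mimosine. This split moved with the scaling. The share lower was 50.4% with the percentile over all miRNAs, 45.7% with median scaling, 57.5% with quantile normalization, 64.6% without scaling, 52.0% with scaling to positive controls and 52.8% in the authors' series matrix. Relative to the median, miR-29c differed by 0.85, miR-29b by 0.88, miR-29c* by 0.60 and miR-29a by 0.47, miR-322* by -0.54, miR-466b by -0.72 and miR-145 by -0.34. The median itself lay between -0.16 and 0.04 over these scalings.

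The miR-17/92 and paralogous clusters, miRNAs linked to proliferation, were called lower as a list at the preset correlation (camera adjusted p = 0.0465, mean log2 difference -0.45). Of the tested members 8 of 8 were lower and 0 passed the threshold over all miRNAs or adjusted over the list alone. The call was lost with an estimated correlation, here 0.75 (camera adjusted p = 0.876), and with fry (adjusted p = 0.364). miR-93 differed by -0.45 (SE 0.19) and miR-17 by -0.62 (SE 0.28), and by -0.30 and -0.35 without L-mimosine 3, -0.22 and -0.26 with normexp, and -0.27 and -0.38 with quantile normalization. miR-93 differed by -0.25 with median scaling and -0.27 in the series matrix, and miR-17 by -0.37 with the mean of the probes' log2 values. The list's camera adjusted p was 0.250 without L-mimosine 3, 0.214 without vehicle 1, 0.122 without vehicle 2 and 0.0544 without vehicle 4. It was 0.0716 with slide row as a block and 0.126 with no filter on dim miRNAs.

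The other 10 lists did not pass. Of the hypoxia-responsive miRNAs, 11 of 13 tested members were lower and 2 higher, or 8 below and 5 above the median of all tested miRNAs (camera adjusted p = 0.505), with miR-322* at -0.71 and miR-24 at -0.29. miR-210, a target of hypoxia-inducible factor, was detected on L-mimosine 3 and vehicle 3 alone and was not tested. Of the profibrotic miRNAs, 2 of 7 were higher and 5 lower, or 4 above and 3 below the median (camera adjusted p = 0.402). miR-192 differed by 0.82 (SE 0.37; 0.51 without vehicle 1) and miR-21 by -0.09 (SE 0.61; -0.78 without vehicle 3 to 0.14 without vehicle 1). The kidney tubule list had 2 of 7 higher and 5 lower, or 3 above and 4 below the median (adjusted p = 0.929), with miR-192 among the higher and miR-196a at -0.39 among the lower. Its median (-0.25) and mean (-0.01) were below 0 while camera's direction was up. In the epithelial miR-200 family 3 of 5 were higher and 2 lower (adjusted p = 0.654), with miR-200c at -0.48 and miR-141 at -0.23 (-0.39 without L-mimosine 4 to -0.10 without L-mimosine 3). Its mean (-0.09) and median (0.09) differed in sign, as did those of the profibrotic list (0.01 and -0.09). The miR-30 family had 6 of 8 higher and 8 above the median (camera adjusted p = 0.152), with miR-30e at 0.26 (0.0496 without L-mimosine 4 to 0.43 without L-mimosine 1) and miR-30d at 0.10 (1.65e-04 without vehicle 1 to 0.16 without vehicle 3). With slide row as a block the list passed (camera adjusted p = 0.0134), and there with an estimated correlation it did not (0.683).

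In the let-7 family 8 of 8 were lower, or 6 below and 2 above the median (adjusted p = 0.402), from let-7i at -0.38 (-0.24 without L-mimosine 4) to let-7b at -0.04. let-7b and let-7c were higher under some scalings and without L-mimosine 4 (0.11 and 0.0450). With slide row as a block the let-7 list passed (camera adjusted p = 0.0362), and there with an estimated correlation it did not (0.683); it also passed with normexp (camera adjusted p = 0.0393), and there too not with an estimated correlation (0.676). With no filter on dim miRNAs the let-7, hypoxia and smooth muscle and fibroblast lists passed (camera adjusted p = 0.00152, 0.00329 and 0.0151), as did that of the Dlk1-Dio3 locus (0.00309, upward), which had too few tested members otherwise. With an estimated correlation none of the 4 did (0.423, 0.270, 0.423 and 0.0954). Without the filter, 202 of the 350 miRNAs compared were detected on no array, and the median log2 difference was 2.26e-16. Among tested miRNAs it was -0.16, and relative to that the let-7, hypoxia and smooth muscle and fibroblast medians were -0.03, -0.06 and -0.09. The calls of these lists therefore do not show a fall beyond that of detected miRNAs. Only 1 of 40 Dlk1-Dio3 members was tested, miR-494 at -0.46, so the upward call shows no rise. The miR-15/16 family was lower in 5 of 5, or 3 below and 2 above the median (adjusted p = 0.654), with miR-322 at -0.61 (-0.95 without vehicle 3 to -0.38 without L-mimosine 3) and miR-15b at -0.35 (-0.54 without L-mimosine 1 to -0.20 without L-mimosine 4). The miR-23/24/27 clusters were lower in 5 of 5, or 3 below and 1 above the median (adjusted p = 0.429), with miR-24 at -0.29 and miR-23a at -0.24 (-0.41 without vehicle 3 to -0.13 without vehicle 1). Of the 12 lists this one had the lowest fry adjusted p (0.0630), and the exact permutation p of its mean was 0.0571 (two-sided, n = 4 each). Among markers of other cells, the leukocyte list was lower in 6 of 7 (adjusted p = 0.654), with miR-142-5p at -0.60 (-0.99 without vehicle 3) and miR-223 at -0.43 (-0.78 without vehicle 3 to -0.26 without vehicle 1). The smooth muscle and fibroblast list was lower in 6 of 6, or 5 below and 1 above the median (adjusted p = 0.429), with miR-145 at -0.50 and miR-152 at -0.58. For these 10 lists 0 members passed the threshold over all miRNAs or adjusted over the list alone, and 0 lists passed with an estimated correlation or fry.

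**Figure D2:**
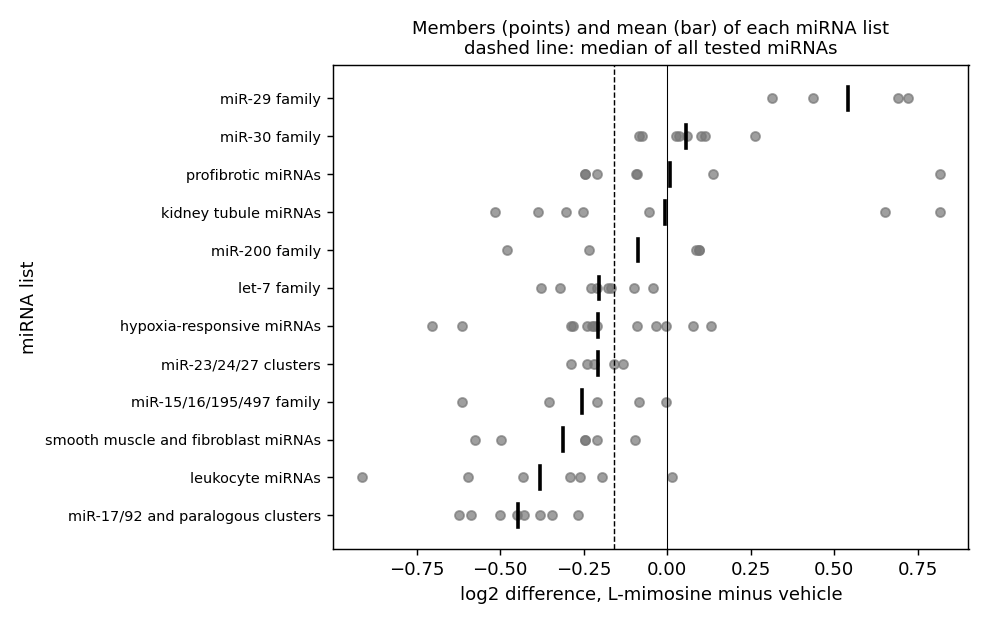
Log2 differences between L-mimosine and vehicle (horizontal axis) are plotted for the tested members of each of 12 lists (vertical axis), as points for members and a bar for the list mean, with n = 4 arrays per group. The miR-29 family mean lies highest at 0.54 and the miR-17/92 clusters lowest at -0.45, and the dashed line marks the median of all tested miRNAs at -0.16.

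Lists with too few tested members gave single values. The erythrocyte miRNA miR-451 differed by -0.75 (SE 0.87), the endothelial miR-126 by -0.01 (SE 0.15) and miR-126* by -0.05 (SE 0.22), the striated muscle miR-499 by 0.23 (SE 0.38) and the adrenal and neuroendocrine miR-7a by -0.03 (SE 0.21). The neuronal miR-128 differed by -0.28 (SE 0.27) and miR-218 by 0.10 (SE 0.27), and miR-494 of the Dlk1-Dio3 locus by -0.46 (SE 0.34). Leaving out 1 array, miR-451 ranged from -1.53 (without vehicle 2) to -0.14 (without vehicle 1), miR-499 from 0.0362 (without vehicle 1) to 0.52 (without L-mimosine 1), miR-128 from -0.52 (without vehicle 3) to -0.13 (without L-mimosine 3) and miR-494 from -0.70 (without vehicle 3) to -0.18 (without vehicle 2). miR-126, miR-126*, miR-7a and miR-218 changed direction. The liver list had no tested member. Of the remaining named miRNAs, miR-25 differed by -0.38 (SE 0.17), miR-125a-5p by -0.38 (SE 0.18), miR-221 by -0.59 (SE 0.29) and miR-199a-3p by -0.25 (SE 0.40; -0.65 without vehicle 3 to 0.0280 without vehicle 1). None of these passed the adjusted threshold.

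The vehicle group was not uniform. Vehicle 3 held miR-21, a miRNA raised in fibrosis and inflammation, at 1.24 on the log2 scale, against 4.01 to 4.03 on the other 3 vehicle arrays and 2.55 to 3.52 on the L-mimosine arrays. Its mean correlation was 0.929 with the other vehicle arrays and 0.958 with the L-mimosine arrays, across miRNAs. Principal component 1 of the 8 arrays held 48.8% of the variance, with vehicle 3 at one end, and did not separate the treatments (exact permutation p = 0.343, two-sided, n = 4 each). Vehicle 3 lay at 5.57, the L-mimosine arrays at -1.60 to 3.04, and vehicles 1, 2 and 4 beyond these at -4.60, -2.50 and -3.44. The overlap of the groups on this component thus rested on vehicle 3. Without vehicle 3, limma gave 43 miRNAs at an unadjusted p under 0.05 and 0 past the adjusted threshold (lowest adjusted p = 0.0522), 4 lists passed camera, and the miR-21 difference was -0.78. The added lists were the leukocyte miRNAs and the miR-30 family (camera adjusted p = 0.0208 each), and with an estimated correlation neither passed there (camera adjusted p = 0.555 each).

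**Figure D3:**
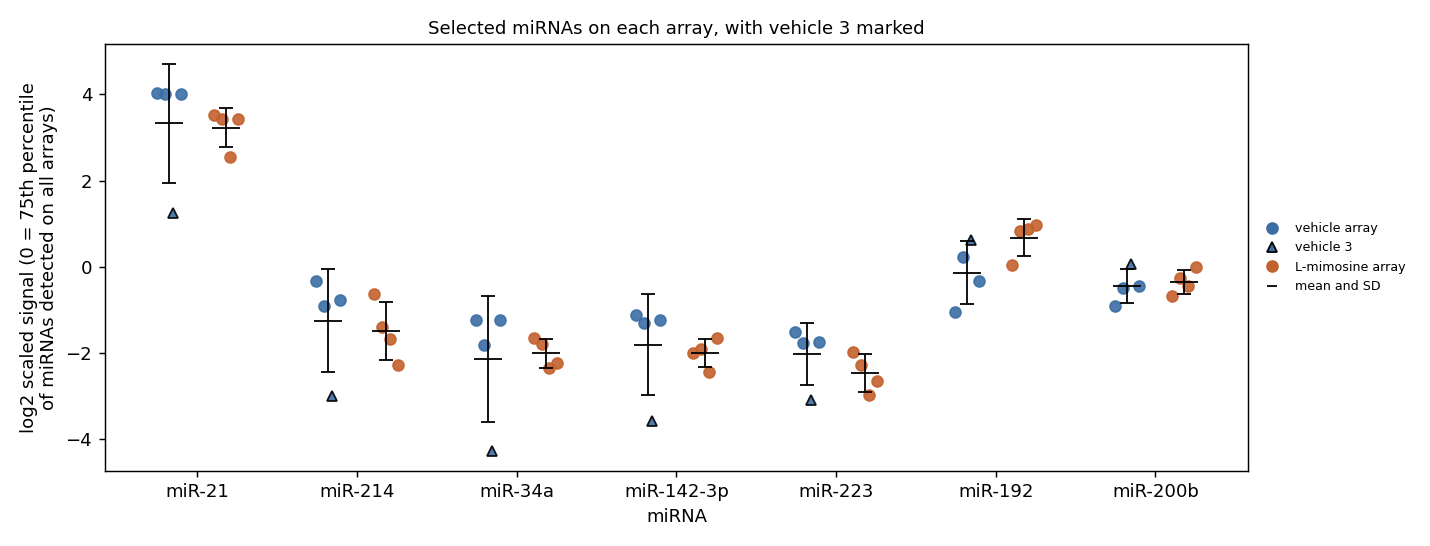
The log2 scaled signal (vertical axis) is plotted per array for 7 miRNAs chosen after their values were seen (horizontal axis), with vehicle arrays in blue, vehicle 3 as a triangle, L-mimosine arrays in orange and bars for mean and SD (n = 4 per group). In miR-21 vehicle 3 lies at 1.24 and the other vehicle arrays at 4.01 to 4.03.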

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

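The tests of array quality, of cell content, of exchanged labels and of probe binding were chosen after the results were seen. Of 94 groups of 4 values, 11 had 1 array far from the others, where chance gives about 1 in 20 (4.70), and 7 of the 11 were in vehicle 3. Vehicle 3 lay low in miR-21 (1.24), miR-322 (-2.94), miR-223 (-3.10), miR-142-5p (-6.15, the floor), miR-15b (-1.005), miR-17 (-3.69) and let-7i (0.0651). L-mimosine 1 lay low in miR-192 (0.0437) and miR-451 (-5.90) and high in miR-125a-5p (-1.51). L-mimosine 3 lay low in miR-21 (2.55). Among the miRNAs too rarely detected to test, miR-374 was detected on 2 L-mimosine arrays and no vehicle array, with a mean of -5.85 over the L-mimosine arrays, close to the floor, while 3 miRNAs showed the opposite.

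In vehicle 3, miR-21 differed from the mean of the other vehicle arrays by -2.78 log2 units, and by -1.93 to -2.78 over 6 scalings. The array was not dim: its 75th percentile signal was 1509, against 877 to 1308 on the other vehicle arrays. Vehicle 3 stood apart in 0 of 6 quality measures. With 4 values per group that test flags only extreme arrays, and no measure read the quality of the RNA, so a poor sample stays open. An exchange of labels with an L-mimosine array cannot be told apart: vehicle 3 lay below the L-mimosine range in 3 of 4 tested miR-29 members, which met the criterion set against an exchange, but that criterion was wrong, since in 2 of these 3 members the array lay below the other vehicle arrays too, and L-mimosine 1 lay within the range of those arrays in 3 of 4. Scaling stays open by its test (smallest gap ratio 0.768, with no scaling, below the 95% value for 4 samples), yet relative to the median miRNA of the same array, which 1 factor per array cannot move, miR-21 differed by -2.69. A lower share of leukocytes and mesenchymal cells in the piece taken is a candidate explanation: the median deviations of vehicle 3, relative to the median of all tested miRNAs, were -1.34 in the leukocyte list and -1.14 in the smooth muscle and fibroblast list, against 0.74 in the miR-200 family and 0.37 in the miR-30 family. Against fewer smooth muscle cells, miR-143 and miR-145 of that list deviated by 0.03 and 0.12 on the same measure. Lists that were not chosen as markers of these cells also lay low: the profibrotic list at -2.17, the miR-15/16 family at -1.01 and the miR-17/92 clusters at -0.56. The profibrotic list includes miR-21 and shares members with the smooth muscle and fibroblast list. A lower share of these cells therefore stays open, as does milder injury, which was not tested.

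The higher miR-29 family with L-mimosine is not explained by scaling, since the mean difference over 6 scalings was never below 0.54. One member binding the probes of the others cannot be told apart: miR-29c*, whose probe shares at most 5 bases in a row with theirs, lay 3.05 SE above the median of all tested miRNAs, which met the criterion against it, but it comes from the precursor of miR-29c, whose probe shares 16 bases in a row with that of miR-29b and 12 with that of miR-29a. Among 35 splits of the 8 arrays into 4 and 4, 1 gave the miR-29 list so small a camera p, the real one, and 2 gave miR-29c so small a p, the real one included. For the list, 1 of 35 is the smallest share the splits can give. Its camera p before adjustment was 4.05e-06 in the real split, and other splits gave 1.08e-05 and 2.36e-05. An effect of L-mimosine also stays open, as a hypothesis, while the list call rested on the preset correlation.

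Of the 35 splits, 35 gave at least the real count of 0 miRNAs past the adjusted threshold (highest other 20), as any split must, so this decides nothing. Chance cannot be excluded for the other 2 counts: 6 gave at least the 12 at an unadjusted p under 0.05 (highest other 53), and 21 gave at least the 2 lists past the threshold (highest other 7). The split with 53 set L-mimosine 1 with vehicles 1, 2 and 4 against the rest, that is, L-mimosine 1 and vehicle 3 exchanged, and is the one with 20 past the adjusted threshold. This split was singled out after the counts were seen, and what sets its arrays apart was not tested. With L-mimosine 1 and vehicle 3 exchanged, a comparison made after seeing the data, the miR-29 list call would be lost (camera adjusted p = 0.108, mean difference 0.34). miR-29c would differ by 0.62 (limma adjusted p = 0.0998), miR-29c* by 0.52 and miR-29b by 0.34, while miR-29a would be lower, at -0.13. The miR-17/92 list would still pass at the preset correlation (camera adjusted p = 0.0295).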

How the results depend on the processing

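Slide row as a block, scaling to positive controls and the estimated correlation within a setting were chosen after seeing the data; slide or scan as a block was not run, as there was 1 of each. miR-29c was higher with L-mimosine in every alternative (0.48 to 0.98) and in none past the adjusted threshold, with limma adjusted p from 0.0752 to 0.997. At the preset correlation the miR-29 list passed camera in every alternative to the data or the fit. With an estimated correlation it passed in none of the 4 alternatives recomputed in that way. There its camera adjusted p was 0.555 without vehicle 3, 0.513 with slide row as a block, 0.0541 with normexp and 0.270 with no filter. Of 1495 recomputed values for 56 named miRNAs and lists, 1409 kept their direction and side of the threshold, 71 reversed, 6 lost the threshold and 9 passed it. The count past the adjusted threshold was 1 with array weights (miR-322*), and 0 in the other alternatives. The count at an unadjusted p under 0.05, 12 as reported, was 6 with median scaling, 2 with no scaling, 3 with normexp, 44 with array weights, 7 with positive controls and 6 to 43 leaving out 1 array. The lists past the threshold, 2 as reported, were 5 with no filter on dim miRNAs, where lists were compared mostly with undetected miRNAs. They were 0 with an estimated correlation, 0 with fry's direction p, 0 with its mixed p, and 1 to 4 leaving out 1 array. The miR-17/92 clusters had camera adjusted p 0.126 with no filter and 0.0716 with slide row as a block. The cause was not tested. Whether the replicate numbers pair the arrays cannot be told from so few values. Deviations of same-numbered arrays correlated at 0.33, -0.06, 0.44 and -0.29, and 3 arrays correlated best with their own number. With the replicate block 24 miRNAs had an unadjusted p under 0.05, and 0 passed the adjusted threshold (lowest limma adjusted p = 0.146). The SE of the miR-29c difference was 0.19 with that block and 0.25 as reported.

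With the percentile over all miRNAs, miR-126* gave 0.0938, miR-126 0.13, miR-7a 0.11, miR-21 0.0501, let-7c 0.0465 and let-7b 0.10. With median scaling they gave 0.15, 0.18, 0.16, 0.10, 0.0988 and 0.15, and let-7a 0.0274. With quantile normalization miR-141 gave 0.0542, miR-126* 0.27, miR-7a 0.34, miR-21 0.25, let-7c 0.26 and the miR-200 list -0.0113. With no scaling miR-126* gave 0.0140, miR-126 0.0349, miR-7a 0.0761 and let-7b 0.00440. With positive controls miR-126* gave 0.0672, miR-126 0.11, miR-7a 0.0853, miR-21 0.0236, let-7c 0.0200 and let-7b 0.0754. In the authors' matrix miR-142-5p gave 0.0588, miR-126* 0.10, miR-7a 0.22, miR-21 0.29, let-7c 0.17 and the miR-200 list -0.13. With slide row as a block miR-126* gave 0.24, miR-126 0.13, miR-7a 0.0151 and the profibrotic list -0.10. Array weights gave miR-451 0.23 and the profibrotic list -0.11, normexp gave miR-126* 0.00817, the doubled floor gave miR-7a 0.0113, no filter gave the miR-200 list -0.0141 and the scanner's detection flag gave the hypoxia list 0.00686. List values are differences from the other miRNAs.

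Leaving out 1 array, 26 of 444 values reversed: miR-199a-3p ranged from -0.65 to 0.0280, miR-126* from -0.22 to 0.0478, miR-126 from -0.0890 to 0.0391, miR-7a from -0.14 to 0.0504, miR-218 from -0.0427 to 0.31, miR-21 from -0.78 to 0.14, let-7c from -0.20 to 0.0450 and let-7b from -0.15 to 0.11. Among lists the profibrotic ranged from -0.20 to 0.33, miR-200 from -0.0341 to 0.20, let-7 from -0.17 to 0.0920, miR-15/16 from -0.33 to 0.0209 and smooth muscle and fibroblast from -0.42 to 0.0409. The number of detected miRNAs per array differed by -10.9 to 1.08 between the groups. Signal over background limits the dim miRNAs, whose values lie near the floor.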

Other observations

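The miRNAs that varied most within groups, chosen after their values were seen, were led by 4 that lay low in vehicle 3. Among miRNAs detected on all 8 arrays, miR-34a had a within-group SD of 1.06 log2 units, miR-21 1.03, miR-214 0.97 and miR-142-3p 0.86, against a median of 0.32 over the tested miRNAs. In vehicle 3 they differed from the other vehicle arrays by -2.86, -2.78, -2.33 and -2.35. miR-194, miR-192 and miR-204 were also among the 12 most variable. Across the 8 arrays miR-21 followed the mean of the leukocyte list (Pearson r = 0.939, permutation p = 3.47e-04, adjusted 0.00139; Spearman rho = 0.952, permutation p = 0.00114, adjusted 0.00456; 4 relations computed). These 4 relations were not among the tests fixed before the data were examined, so their p-values do not allow for that choice. Without vehicle 3 and L-mimosine 3, the arrays farthest from the median in miR-21, r with the leukocyte list was 0.950. With group means removed it was 0.983, and within slide rows 1 and 2 it was 0.991 and 0.941 (4 arrays each). The others gave no adjusted p below the threshold: miR-21 with the miR-200 family mean (r = -0.312, permutation p = 0.480; rho = -0.381, permutation p = 0.360), with miR-29c (r = -0.0212, permutation p = 0.962; rho = -0.405, permutation p = 0.327) and with miR-192 (r = -0.527, permutation p = 0.176; rho = -0.762, permutation p = 0.0368, adjusted 0.0735). Without the same 2 arrays these r were -0.186, -0.721 and -0.781, so the value with miR-29c depends on them. miR-34a and miR-214, outside the leukocyte list, also lay low in vehicle 3. The relation of miR-21 to that list is therefore not shown to be particular to leukocyte miRNAs.

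miRNAs whose genes neighbour each other differed alike between the treatments. Over 47 pairs within 10 kb the mean gap between their log2 differences was 0.11, against 0.35 over all pairs (one-sided permutation p = 1e-05, the smallest the permutations can give). Examples are miR-192 and miR-194 at 0.82 and 0.65, and miR-200a and miR-200b at 0.09 and 0.09, while 2 pairs lay farther apart than the mean of all pairs, miR-143 and miR-145 at -0.10 and -0.50 and miR-29a and miR-29b at 0.31 and 0.72. Transcription from shared precursors may account for this, as a hypothesis, but neighbours are often related in sequence, and pairs share miRNAs, which this p does not allow for. Of the pairs, 6 did not share a fixed list, with a mean gap of 0.08 (one-sided permutation p = 0.00168). In settings recomputed after seeing the data, the mean gap over the 47 pairs was 0.19 with slide row as a block. Without L-mimosine 1 it was 0.15.

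The 2 arms of a precursor moved alike in the values as reported: relative to the median, both had the same sign in 12 of 12 pairs (exact binomial p = 4.88e-04, two-sided). miR-29c and miR-29c* stood 0.85 and 0.60 above the median, and miR-322 and miR-322* -0.45 and -0.54 from it. The count depended on the processing: in settings recomputed after seeing the data it was 8 of 12 with quantile normalization and 8 of 12 without vehicle 1 (exact binomial p = 0.388 each, two-sided), and 11 of 12 with the floor doubled, where miR-322* changed side. Change in the precursor stays a hypothesis, as both arms of a pair were measured on the same arrays and 3 of the 12 pairs were of the miR-30 family.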
